A study of Mus musculus with 6 samples.

How the data were processed

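Total RNA from day 8 cultures was extracted with Trizol, amplified and labelled with biotin for Affymetrix whole-transcript gene arrays, per the labels' protocols. The 6 arrays fell into a vehicle group and a 4-OHT group of 3 arrays each by their titles. The group given 4-OHT is labelled as Hdac3 depletion. The labels number replicates within each group, and nothing in them says that the numbers stand for separate cultures, so p-values measure the spread between these arrays, which may be partly technical. No 4-OHT culture without Cre or without loxP sites is among these arrays, so effects of the drug, of activated Cre and of Hdac3 loss are not separated. The labels' growth protocol describes stem cells derived from Hopx mutant blastocysts, while the series design describes the floxed Hdac3 line, and the design was followed for the groups.

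The deposited values are log2 expression values, 1 per transcript cluster and array. Per the submitters' processing notes they were made with RMA and Partek 6.6. RMA corrects background, quantile-normalizes probes between arrays and summarizes the probes of each transcript cluster. The log base is not written in the sources used here. Values between 2.04 and 13.6 were read as log2, as RMA gives them. The medians of the deposited columns were 4.69, 4.81 and 4.70 for vehicle and 4.76, 4.77 and 4.75 for 4-OHT. The values are of single-colour arrays, so no ratio direction was involved, and genes were not centred. Any probe filter and the test the submitters used are not given in the sources used here. Precision is limited by the number of arrays and, for dim genes, by signal close to background. No detection calls were used here.

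Of 41345 transcript clusters, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 were not listed there. Clusters with 1 symbol were used, and the cluster with the highest mean over all arrays stood for a gene with several clusters, which gave 22180 genes. The remaining 17824 clusters were tested separately with limma: 0 passed an adjusted p of 0.05 and 534 had an unadjusted p under 0.05, where chance would give 891.2. Gene lengths, classes and neighbours came from a RefSeq gene table of the GRCm38.p6 assembly, matched by gene identifier for 99.2% of genes. No coordinates are given, because the build behind the array annotation is not named in the sources used here.

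Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The moderated test had 6.77 degrees of freedom. The median residual SD was 0.20 and the median SE of a difference 0.16. Differences are log2 means of 4-OHT minus vehicle, and folds are 2 to that power. Hdac3 was also tested with a two-sided exact permutation test. Gene lists were tested with camera, which compares a list's genes with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation and fry stood beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

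The lists were fixed before the data were examined: sarcomere, calcium handling and conduction, cardiac transcription factor, second heart field, early mesoderm, smooth muscle, skeletal muscle, endothelial, blood, epicardial and mesothelial, fibroblast, neural, neural crest, endoderm, epithelial, pluripotency, germ cell, HDAC3 corepressor, nuclear lamina and heterochromatin, G2 and M phase, S phase, p53 target, interferon, TGF-beta and BMP, Notch, Wnt target, fatty acid, glycolysis and hypoxia, sterol, amino acid response, endoplasmic reticulum chaperone, estrogen and xenobiotic, circadian, Hox, imprinted, mitochondrial RNA and ribosomal protein genes. Of 785 entries 718 were measured, 12 of them under another name. The mitochondrial names were matched by hand once the array's names were seen.

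The rule for named genes was fixed at the same time. It named Hdac3, then the 12 genes with the largest rise and fall among those past the threshold whose groups did not overlap or, if none passed, the 5 with the smallest p in each direction. It left out 4858 genes with clone, predicted or small RNA names. It named up to 4 members of each list by smallest p where a list held a member past the threshold, and gave other lists by their counts only. Since 0 genes passed, every list member named beyond that rule, and the arrays' values set beside it, was chosen after its values were seen.

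The procedure was tested on simulated data for this comparison, with 200 of 22180 genes changed. With each gene's SD as measured here, 52% of 2-fold and 82% of 4-fold changes were recovered, with 5 false calls. The simulated noise was normal and independent between genes, whereas 2 of the real arrays carried shifts shared by many genes. These rates therefore need not hold for the real arrays.

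Alternatives fixed beforehand were equal array medians, a further quantile normalization, a filter at the median level, a trended robust variance, no variance moderation, array weights, the mean of a gene's clusters, a test of every cluster, a replicate block, and leaving out each array in turn. Those chosen after seeing the data were leaving out both arrays that stood apart, the small nucleolar RNA level as a covariate, and removal of each array's trend with gene length by lowess with a span of 0.3. The shortest and longest genes were each 1 in 6 of the protein-coding genes at or above the median level.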

Results

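Hdac3, the histone deacetylase of the NCoR and SMRT corepressor complexes, was targeted for deletion during cardiac differentiation of mouse embryonic stem cells. RNA was profiled on Affymetrix gene arrays. The stem cell line carried loxP-flanked Hdac3 and a Cre recombinase fused to an estrogen receptor domain, which 4-hydroxytamoxifen (4-OHT) moves into the nucleus. Cells were differentiated as embryoid bodies, small aggregates that form heart muscle together with other cell types. Vehicle or 4-OHT at 1 µg/ml was added at day 5 and RNA was taken at day 8, with 3 arrays of each group. The median log2 value of the arrays lay between 4.69 and 4.81, and their number limits the precision. The series title names myogenesis as its subject, so the comparison asks how depletion of Hdac3 in these cultures bears on muscle gene expression.

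Hdac3 itself was lower in each of the 3 arrays of the 4-OHT group than in any vehicle array. Its log2 value was 8.86 ± 0.47 (SD, n = 3) with vehicle and 7.21 ± 0.33 (SD, n = 3) with 4-OHT. The difference of -1.66 (SE 0.27, 95% interval -2.31 to -1.01) left 31.7% of the vehicle level. Per array, Hdac3 measured 9.22, 8.33 and 9.03 with vehicle and 7.59, 6.97 and 7.06 with 4-OHT. Hdac3 ranked 3 among all genes by p, but limma's Benjamini-Hochberg adjusted p was 0.969. A two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The array measured Hdac3 with a single transcript cluster whose exon positions are not known here, so the share of signal from undeleted exons is open. Without vehicle replicate 2 and 4-OHT replicate 1, which stood apart from the other arrays and were left out after the data were seen, the difference was -2.11 and limma's adjusted p was 0.0515, within a range of 0.0515 to 1.00 over all settings tried.

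Heart muscle contraction genes were higher with 4-OHT as a group in camera's test with its preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.901 with an estimated correlation). Their median log2 difference of 0.27 depended on single arrays: it was 0.033 without vehicle replicate 1, 0.066 without 4-OHT replicate 3 and 0.71 without vehicle replicate 2. The ventricular and slow-muscle light chain gene Myl3 was 2.21-fold higher, the cardiac troponin I gene Tnni3 2.06-fold and the ventricular light chain gene Myl2 1.76-fold. Genes of the p53 response, such as the death receptor gene Fas (2.38-fold higher), were also higher as a group, and genes of the G2 and M phases, such as the proliferation marker Mki67 (2.07-fold lower), were lower as a group. These lists too passed camera's test with its preset correlation and lost the call with an estimated correlation. No single gene passed limma's test over all genes.

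In limma's fit 0 of 22180 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.969. At an unadjusted p under 0.05 there were 713 genes, 326 higher and 387 lower, where chance would give 1109. Without vehicle replicate 1 that count was 410, and without both arrays that stood apart it was 1617, again with 0 genes past the adjusted threshold. Every other fit tried also gave 0 genes. The 3 arrays of one group lay wholly above those of the other for 1064 genes higher and 964 genes lower with 4-OHT, which is 9.14% of genes against the 10% that chance gives. Group means differed at least 2-fold upward for 76 genes and downward for 16.

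The genes with the smallest p in each direction did not pass the adjusted threshold (limma adjusted p = 0.969 for each), and each was higher or lower in 3 of 3 arrays. Upward these were Myl3 (6.53 ± 0.16 against 7.67 ± 0.22, SD, n = 3), Ndnf, Kdelr3, Cox6a2 and Tcim. Cox6a2, the heart and skeletal muscle form of a cytochrome c oxidase subunit, was 2.74-fold higher, with a log2 difference of 1.46 (SE 0.28). Ndnf, a secreted neurotrophic factor, differed by 0.77 (SE 0.12) and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, by 0.78 (SE 0.14). Tcim differed by 0.70 (SE 0.14). Downward, after Hdac3, these were Poglut3, a protein glucosyltransferase gene, at -0.73 (SE 0.15), Gphn, which encodes the synaptic scaffold gephyrin, at -0.60 (SE 0.13), Wdr92 at -0.58 (SE 0.12) and Wdr55 at -0.58 (SE 0.13).

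**Figure D1:**
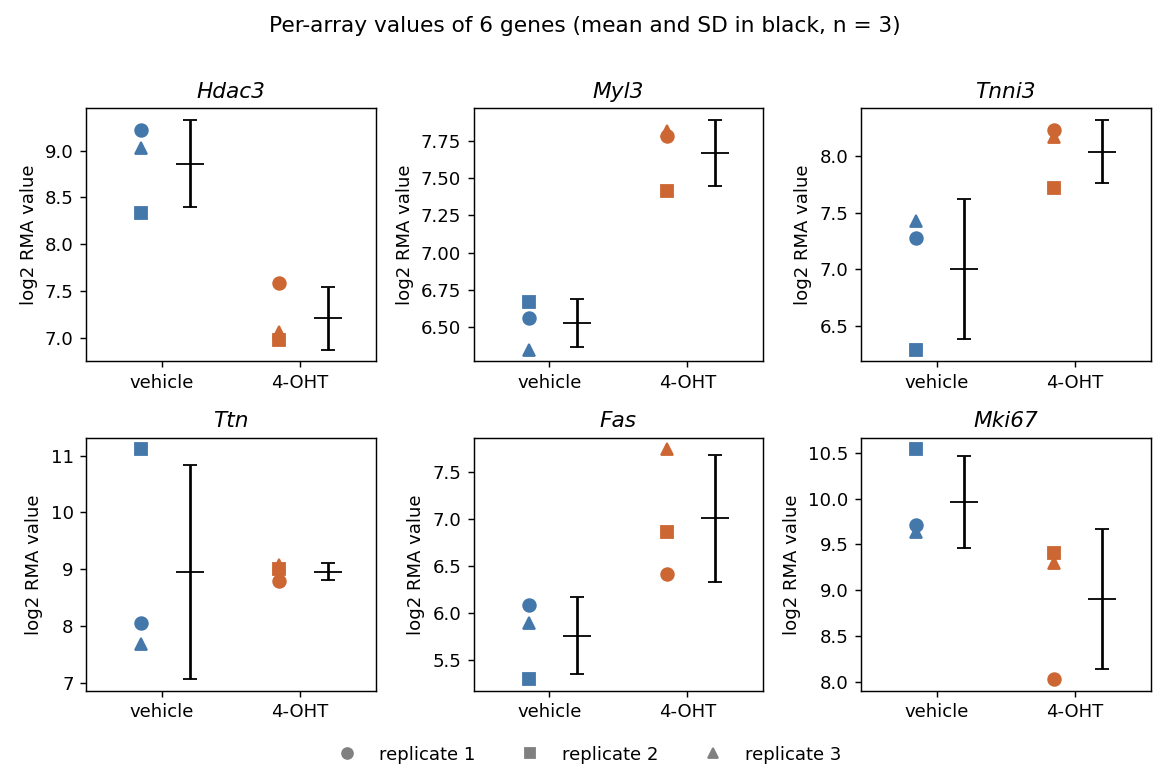
Log2 RMA values of 6 genes in each array of the vehicle and 4-OHT groups (points, shaped by replicate number), with the mean and SD of 3 arrays beside them. Hdac3 lies lower and Myl3 higher in all 3 arrays with 4-OHT, while Ttn ranges from 7.68 to 11.1 among the vehicle arrays.

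Among 26 sarcomere genes, 21 were higher and 5 lower with 4-OHT, with a median log2 difference of 0.27 (camera adjusted p = 3.09e-05, and adjusted p = 0.901 with an estimated correlation). Adjusted over the list alone, 1 member passed, Myl3, with a difference of 1.14 (SE 0.16) and limma's adjusted p = 0.00491, against 0 members over all genes. The next members by p were Myl2 at 0.81 (SE 0.20), Smpx, a small muscle protein gene, at 0.84 (SE 0.22), and Tnni3 at 1.04 (SE 0.32), each higher in 3 of 3 arrays. Some other members had group means close together but with large SEs. Titin (Ttn) differed by 0.01 (SE 0.84) and the myosin heavy chain gene Myh6 by 0.01 (SE 0.59). Cardiac troponin T (Tnnt2) differed by 0.03 (SE 0.50). The spread of these genes came with vehicle replicate 2. Ttn was 11.1 there against 8.05 and 7.68 in the other vehicle arrays and between 8.79 and 9.08 with 4-OHT. Without that array all 26 sarcomere genes were higher with 4-OHT, with a median of 0.71, and Ttn differed by 1.09 (SE 0.17). Without both arrays that stood apart the median was 0.86, with Actn2, which encodes the Z-disc protein alpha-actinin, 2.83-fold higher, Des (desmin) 2.21-fold and Tnnt2 1.86-fold. The median also moved to 0.033 without vehicle replicate 1, to 0.12 without vehicle replicate 3 and to 0.066 without 4-OHT replicate 3, and stayed past camera's preset-correlation threshold in each of these fits.

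Other heart genes did not pass. Of 21 calcium handling and conduction genes, 14 were higher, with a median of 0.12 (camera adjusted p = 0.253). Among them the calcium pump regulator phospholamban (Pln) was 7.00 ± 1.42 with 4-OHT and 5.65 ± 0.51 with vehicle (SD, n = 3), and the connexin gene Gja5 was higher in 3 of 3 arrays by 0.29 (SE 0.13). Without vehicle replicate 2 this list had a median of 0.23 (camera adjusted p = 9.27e-06, and adjusted p = 0.522 with an estimated correlation). Without 4-OHT replicate 3 it was 0.0011, with 11 genes higher and 10 lower, and without vehicle replicate 1 or 3 it was 0.047 and 0.043. Cardiac transcription factors had a median of -0.19, with 7 members higher and 15 lower (camera adjusted p = 0.253). Mef2c differed by -0.84 (SE 0.45), Hey2 by -0.61 (SE 0.45) and Isl1 by -0.52 (SE 0.45). The transcription factor median was -0.40 without vehicle replicate 3 (camera adjusted p = 0.0137, and adjusted p = 0.843 with an estimated correlation) and turned to 0.057 without vehicle replicate 2, the array in which Mef2c read 9.02 against 7.79 and 7.39 in the other vehicle arrays. Second heart field genes had a median of -0.037 (camera adjusted p = 0.533), with the forkhead gene Foxc1 at -0.56 (SE 0.18) and its relative Foxc2 at 0.57 (SE 0.21). Early mesoderm genes had a median of 0.065 (camera adjusted p = 0.874). With 1 array left out the second heart field median ran from -0.12 without 4-OHT replicate 1 to 0.019 without 4-OHT replicate 3, and the early mesoderm median from -0.073 without 4-OHT replicate 1 to 0.14 without 4-OHT replicate 2.

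The other muscle lists did not pass either. Smooth muscle genes had a median of 0.11, with 10 of 15 higher (camera adjusted p = 0.497), and Tagln, which encodes an actin-binding protein, was higher in 3 of 3 arrays by 0.58 (SE 0.28). Skeletal muscle genes had a median of 0.049, with 17 of 27 higher (camera adjusted p = 0.135), led by the calcium-binding gene Casq1 at 0.61 (SE 0.20). The myogenic regulator Myog differed by 0.43 (SE 0.21). Without vehicle replicate 3 the skeletal muscle median was 0.10 (camera adjusted p = 0.0359, and adjusted p = 0.821 with an estimated correlation). It was 0.028 without vehicle replicate 2 and 0.033 without 4-OHT replicate 1, uncalled in both. The smooth muscle median turned to -0.015 without vehicle replicate 3.

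Of 21 p53 target genes 17 were higher, and 9 of them were higher in 3 of 3 arrays. Their median log2 difference was 0.33 (camera adjusted p = 1.59e-05, and adjusted p = 0.901 with an estimated correlation). Fas differed by 1.25 (SE 0.36), Phlda3, an inhibitor of Akt signalling, by 0.60 (SE 0.20), the stress gene Sesn2 by 0.49 (SE 0.16) and Perp, a cell death effector, by 0.40 (SE 0.14). Adjusted over the list alone 0 members passed in limma's fit, as over all genes, while 6 had an unadjusted p under 0.05. The cell cycle inhibitor Cdkn1a differed by 0.61 (SE 0.45), with 9.98 in vehicle replicate 2 against 8.30 and 8.54 in the other vehicle arrays. Without 4-OHT replicate 3 the p53 median was 0.22.

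Of 24 G2 and M phase genes 20 were lower, with a median of -0.44 (camera adjusted p = 1.59e-05, and adjusted p = 0.901 with an estimated correlation). The mitotic kinase gene Aurkb differed by -0.44 (SE 0.12), the checkpoint gene Bub1b by -0.44 (SE 0.16), Mki67 by -1.05 (SE 0.42) and the spindle gene Nusap1 by -0.75 (SE 0.30), each lower in 3 of 3 arrays. Adjusted over the list alone 0 members passed in limma's fit, as over all genes, and 4 had an unadjusted p under 0.05. Mki67 read 8.03 in 4-OHT replicate 1 against 9.40 and 9.29 in the other 4-OHT arrays. The median was -0.21 without 4-OHT replicate 1 and -0.72 without 4-OHT replicate 2. S phase genes had a median of -0.024, with 11 higher and 14 lower (camera adjusted p = 0.535), and -0.20 without vehicle replicate 2 (camera adjusted p = 7.64e-05, and adjusted p = 0.522 with an estimated correlation). The S phase median turned to 0.045 without vehicle replicate 1, 0.056 without vehicle replicate 3 and 0.0036 without 4-OHT replicate 1, uncalled in each.

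Amino acid response genes, targets of the transcription factor ATF4, were higher in 18 of 21 cases, with a median of 0.24 (camera adjusted p = 0.00422, and adjusted p = 0.901 with an estimated correlation). Ddit3, which encodes the stress factor CHOP, differed by 0.66 (SE 0.14) and was the only member to pass adjusted over the list alone (limma adjusted p = 0.0463), against 0 over all genes. Atf3 differed by 0.46 (SE 0.16) and Sesn2, which the p53 list also holds, by 0.49 (SE 0.16), whereas the lipoprotein receptor gene Vldlr differed by -0.42 (SE 0.13). The call was lost without vehicle replicate 2 (median 0.058), without 4-OHT replicate 1 (median 0.10) and with array weights (median 0.074, camera adjusted p = 0.0823). Of 15 sterol synthesis genes 12 were lower, with a median of -0.14 (camera adjusted p = 0.0235, and adjusted p = 0.901 with an estimated correlation), led by lanosterol synthase (Lss) at -0.80 (SE 0.29) and Insig1 at -0.54 (SE 0.22). The sterol call was lost without vehicle replicate 2 (median -0.032) and without 4-OHT replicate 1 (median -0.12), and its median was -0.21 without vehicle replicate 1. It was also lost with a further quantile normalization (median -0.11, camera adjusted p = 0.0632), a filter at the median level (0.120), a trended robust variance (0.0559), array weights (median -0.069, 0.163) and the gene length trend removed (median -0.080, 0.135).

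Hox genes were higher in 33 of 36 cases, by a small median of 0.10 (camera adjusted p = 0.00422, and adjusted p = 0.901 with an estimated correlation), with Hoxc6 at 0.52 (SE 0.20) and Hoxd10 at 0.31 (SE 0.14). The call was lost without vehicle replicate 2 (median 0.033) and without 4-OHT replicate 1 (median 0.044), and the median was 0.17 without vehicle replicate 1 and 0.19 without 4-OHT replicate 3. With the gene length trend removed the Hox median was 0.00081, with 18 genes higher and 18 lower (camera adjusted p = 0.663), and with array weights it was 0.021 (0.317). Ribosomal protein genes, listed as a sign of RNA quality, were higher in 17 of 21 cases, with a median of 0.24 (camera adjusted p = 0.0127, and adjusted p = 0.901 with an estimated correlation). Their median against each gene's mean was -0.54 in vehicle replicate 2 and between 0.015 and 0.23 in the other arrays. The ribosomal call was lost without vehicle replicate 2 (median 0.023) and without 4-OHT replicate 2 (median 0.24), and the median was 0.36 without vehicle replicate 3. It was also lost with a further quantile normalization (median 0.14, camera adjusted p = 0.0846), array weights (median 0.042, 0.317) and the gene length trend removed (median 0.12, 0.256). Adjusted over the list alone, 0 members of the sterol, Hox or ribosomal lists passed in limma's fit, and 3, 1 and 0 had an unadjusted p under 0.05. Transcripts of the mitochondrial genome had a median of -0.090, with 9 of 10 lower (camera adjusted p = 0.244), and -0.15 without 4-OHT replicate 3 (camera adjusted p = 0.0480, and adjusted p = 0.912 with an estimated correlation). Without 4-OHT replicate 1 the mitochondrial median was -0.0045, with 5 of 10 lower, and with the gene length trend removed it was -0.28, with 10 of 10 lower (camera adjusted p = 0.00305, and adjusted p = 0.849 with an estimated correlation).

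Markers of other cell types that embryoid bodies can hold did not pass camera's test. Blood cell genes had a median of -0.21, with 12 of 18 lower (camera adjusted p = 0.139). The embryonic globin gene Hbb-bh1 was 6.38 in 4-OHT replicate 3 and between 9.23 and 11.3 in the other arrays. Endoderm genes had a median of -0.16, with 14 of 21 lower (camera adjusted p = 0.281), and the fibrinogen gene Fgg was lower in 3 of 3 arrays by -0.61 (SE 0.19). Fgg was dim, with means of 4.57 with vehicle and 3.96 with 4-OHT, below every array's median. Endothelial genes had a median of 0.018 (camera adjusted p = 0.698), with the vascular receptor gene Tek at -0.61 (SE 0.24). Without 4-OHT replicate 1 these lists passed, with medians of -0.37 for blood (camera adjusted p = 3.50e-05), -0.42 for endoderm (0.00144) and -0.16 for endothelium (0.00157), and each had adjusted p = 0.814 with an estimated correlation. Without 4-OHT replicate 3 the medians turned upward for blood (0.042) and endoderm (0.087), and the endothelial median rose to 0.12. The blood, endoderm and endothelial lists did not pass there, and endoderm was also at 0.039 without vehicle replicate 1. Fibroblast genes had a median of 0.13, with 14 of 19 higher (camera adjusted p = 0.253), and a median against each gene's mean of 0.50 in 4-OHT replicate 3. They passed without vehicle replicate 1 (median 0.21, adjusted p = 0.930 with an estimated correlation in camera) and without 4-OHT replicate 2 (median 0.30, adjusted p = 0.789 with an estimated correlation). Without 4-OHT replicate 3 the fibroblast median turned to -0.089, with 9 genes higher and 10 lower, and without vehicle replicate 2 it was 0.025. Epicardial and mesothelial genes had a median of 0.034 (camera adjusted p = 0.159), with Upk1b at 0.67 (SE 0.25) and the regulator Wt1 at 0.34 (SE 0.15), and 0.12 without 4-OHT replicate 2 (camera adjusted p = 0.0382, and adjusted p = 0.789 with an estimated correlation). Without 4-OHT replicate 1 the epicardial median turned to -0.014. The epicardial list also passed with a filter at the median level (median 0.37, camera adjusted p = 0.0117, and adjusted p = 0.702 with an estimated correlation). That filter left 6 of its 13 genes, so this median is of a smaller set. It passed as well with the gene length trend removed (median 0.16, camera adjusted p = 0.0268, and adjusted p = 0.849 with an estimated correlation). Epithelial genes had a median of 0.086, with 14 of 18 higher (camera adjusted p = 0.110), led by the keratin genes Krt18 at 0.39 (SE 0.12) and Krt8 at 0.38 (SE 0.12), both higher in 3 of 3 arrays. The epithelial list passed without vehicle replicate 3 (median 0.076, adjusted p = 0.843 with an estimated correlation in camera) and without 4-OHT replicate 2 (median 0.22, adjusted p = 0.789 with an estimated correlation). The epithelial median was 0.039 without vehicle replicate 2, 0.047 without 4-OHT replicate 1 and 0.027 without 4-OHT replicate 3, uncalled in each. Medians were 0.0024 for neural genes (camera adjusted p = 0.683), 0.057 for neural crest genes (0.698), -0.0030 for pluripotency genes (0.962) and -0.034 for germ cell genes (0.944). With 1 array left out these medians ran from -0.087 to 0.098 for neural, -0.00069 to 0.13 for neural crest, -0.13 to 0.20 for pluripotency and -0.085 to 0.052 for germ cell genes. Among pluripotency genes Prdm14 differed by -0.35 (SE 0.10) and Klf4 by 0.45 (SE 0.14). Prdm14 was dim, with means of 4.45 with vehicle and 4.10 with 4-OHT, below every array's median.

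HDAC3's corepressor partners and the other histone deacetylases had a median of -0.043, with 6 of 13 higher (camera adjusted p = 0.630), and Hdac2 read 8.62 in 4-OHT replicate 1 against 9.81 to 10.1 in the other arrays. Nuclear lamina and heterochromatin genes had a median of -0.20, with 13 of 19 lower (camera adjusted p = 0.114). The lamin B1 gene Lmnb1 differed by -0.36 (SE 0.12) and Tmpo by -0.40 (SE 0.19), both lower in 3 of 3 arrays. This list passed without vehicle replicate 3 (median -0.22, adjusted p = 0.821 with an estimated correlation in camera) and without 4-OHT replicate 3 (median -0.23, adjusted p = 0.912 with an estimated correlation). Without 4-OHT replicate 1 the lamina median was -0.096 (camera adjusted p = 0.399). TGF-beta and BMP genes had a median of -0.036 (camera adjusted p = 0.836), with the BMP target Id3 at 0.55 (SE 0.15). Their median was -0.15 without vehicle replicate 3 and turned to 0.076 without vehicle replicate 2, uncalled in both. Medians were 0.024 for Notch genes (camera adjusted p = 0.962), -0.050 for Wnt targets (0.857) and 0.031 for interferon and antigen presentation genes (0.497). With 1 array left out they ran from -0.065 to 0.058 for Notch, -0.14 to 0.00058 for Wnt and -0.028 to 0.097 for interferon genes. Imprinted genes had a median of -0.033 (camera adjusted p = 0.660), which turned to 0.25 without both arrays that stood apart (camera adjusted p = 6.70e-05, and adjusted p = 0.729 with an estimated correlation). Circadian genes had a median of -0.096 (camera adjusted p = 0.805), which turned to 0.062 without vehicle replicate 2, 0.011 without 4-OHT replicate 1 and 0.054 without both arrays that stood apart. Fatty acid genes had a median of 0.043 (camera adjusted p = 0.497), with the lipid droplet gene Plin2 at 0.65 (SE 0.26). Glycolysis and hypoxia genes had a median of -0.14, with 15 of 20 lower (camera adjusted p = 0.253), and passed without vehicle replicate 3 (median -0.23, adjusted p = 0.821 with an estimated correlation in camera) and without 4-OHT replicate 3 (median -0.16, adjusted p = 0.912 with an estimated correlation). The glycolysis median was -0.045 without vehicle replicate 1, -0.023 without vehicle replicate 2 and -0.053 without 4-OHT replicate 2, uncalled in each. Endoplasmic reticulum chaperone genes had a median of -0.047 (camera adjusted p = 0.514). It was -0.18 without 4-OHT replicate 3 (camera adjusted p = 0.0559) and 3.3e-05 without 4-OHT replicate 1. Targets of the estrogen receptor, of which 4-OHT is a ligand, of the aryl hydrocarbon receptor and of oxidative stress had a median of -0.032 (camera adjusted p = 0.824). With 1 array left out this median ran from -0.13 to 0.042. The same ranges were -0.025 to 0.098 for fatty acid, -0.14 to 0.019 for corepressor and -0.10 to 0.12 for imprinted genes.

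**Figure D2:**
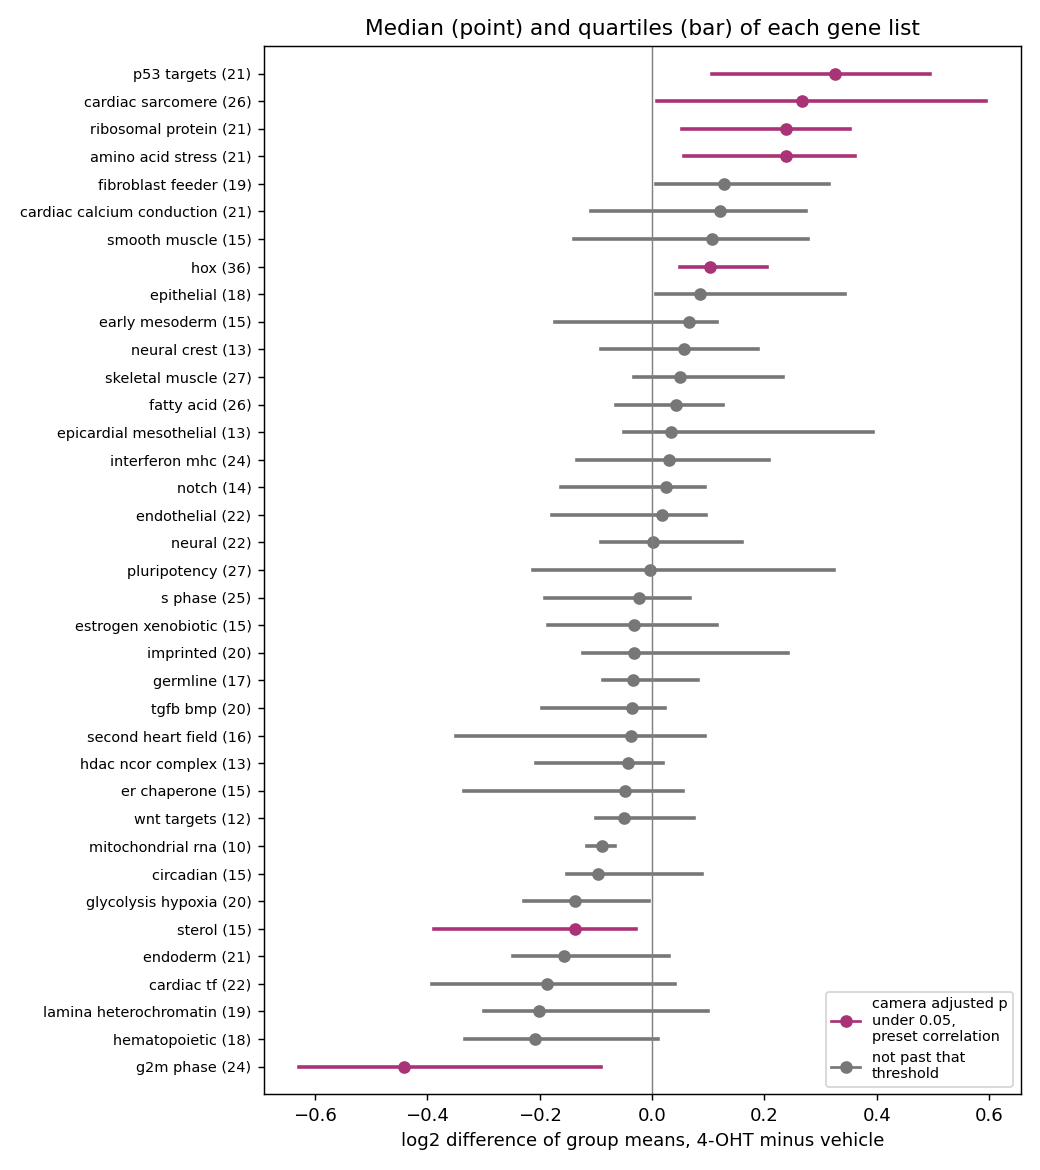
Median (point) and quartiles (bar) of the log2 difference, 4-OHT minus vehicle, over the measured members of each of 37 gene lists, with the number of members in brackets. The 7 lists past camera's threshold with the preset correlation are coloured, from p53 targets at 0.33 down to G2 and M phase genes at -0.44.

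Across the 37 lists camera with its preset correlation called 7, of which 5 were higher and 2 lower with 4-OHT. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05 and a smallest unadjusted p of 0.0526. The rotation test fry also called 0, with 0 at an unadjusted p under 0.05. The amino acid response, sterol, Hox and ribosomal calls were also lost without both arrays, with medians of -0.015, -0.11, -0.022 and -0.0085. They were lost with the small nucleolar RNA level as a covariate too, where 3 of the 7 calls stayed. With 1 array left out the median changed sign at least once for 24 of the 30 lists that did not pass, and for 0 of the 7 that did. The 7 were called on these same arrays, and several of the 30 medians lay near 0 to begin with. This contrast is therefore no independent check of the 7 calls. In 35 of 37 lists 0 members passed adjusted over the list alone. Without vehicle replicate 3 camera called 12 lists, and without both arrays that stood apart it called 11, of which 3 were among the 7. With an estimated correlation it called 0 lists in each of these fits too. The endothelial, pluripotency, germ cell, Notch and imprinted lists each had a median and a mean of opposite sign, and camera's direction followed the mean except for the pluripotency genes.

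The arrays themselves differed within groups. The median of 80 small nucleolar RNA genes, short noncoding RNAs that guide RNA modification, lay at -1.81 against each gene's mean in vehicle replicate 2 and at 1.23 in 4-OHT replicate 1, and between -0.077 and 0.33 in the other arrays. The same arrays stood apart in gene length: the shortest sixth of protein-coding genes minus the longest sixth was -0.37 in vehicle replicate 2, 0.55 in 4-OHT replicate 1 and between -0.10 and 0.0029 elsewhere. The group difference of the small nucleolar RNAs had a median of 0.82. The sarcomere list's median against each gene's mean was 0.56 in vehicle replicate 2 and -0.53 and -0.55 in the other vehicle arrays, and the cardiac transcription factors there were at 0.78. The G2 and M phase list was at -0.82 in 4-OHT replicate 1 and at 0.17 and -0.17 in the other 4-OHT arrays. Correlations between arrays over all genes ran from 0.942, between the arrays that stood apart, to 0.994.

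**Figure D3:**
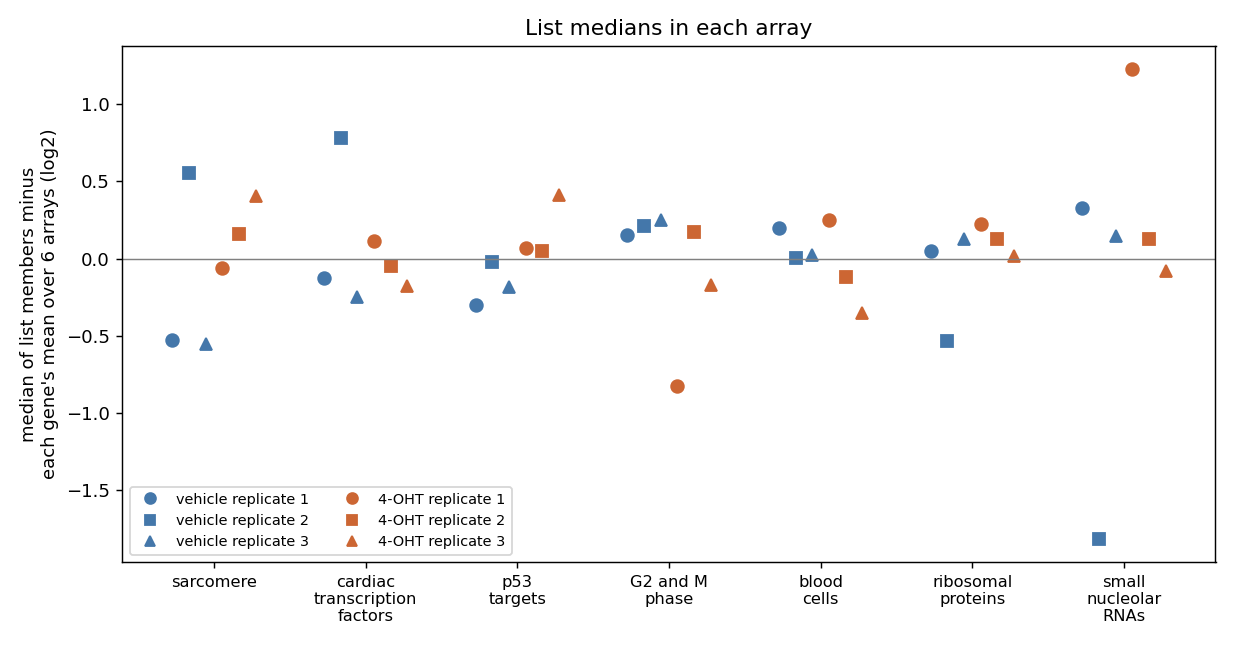
Median over the members of 6 gene lists and of the small nucleolar RNAs in each array, as the log2 value minus each gene's mean over 6 arrays, with vehicle and 4-OHT arrays coloured apart and shaped by replicate number. Vehicle replicate 2 lies at 0.56 for the sarcomere list and at -1.81 for small nucleolar RNAs, and 4-OHT replicate 1 at -0.82 for the G2 and M phase list and at 1.23 for small nucleolar RNAs.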

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

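The refits that left out both arrays that stood apart, used the small nucleolar RNA level as a covariate or removed the trend with gene length were chosen after seeing the data. The counts of genes higher, lower and changed at least 1.5-fold were 0 in limma's fit and 0 under every alternative, with 296 to 1617 genes at an unadjusted p under 0.05. At an adjusted p of 0.10 the fit to all 6 arrays also gave 0 genes, while Hdac3 passed that looser threshold without both arrays (limma adjusted p = 0.0515) and with the covariate (0.0616). Hdac3 kept its direction and stayed above an adjusted p of 0.05 under every alternative, between -2.11 and -1.48, and between -1.92 and -1.48 with 1 array left out. The sarcomere, p53 and G2 and M phase lists kept their direction and their camera call in every refit, with ranges of 0.033 to 0.71, 0.22 to 0.41 and -0.72 to -0.21 with 1 array left out. Their medians of 0.27, 0.33 and -0.44 were no longer called by camera with an estimated correlation or by fry, which called 0 lists each. These tests allow for the correlation among a list's genes. With 1 array left out the count of lists past the threshold ran from 5 to 12, the calcium handling median from 0.0011 to 0.23, the cardiac transcription factor median from -0.40 to 0.057, the smooth muscle median from -0.015 to 0.20 and the skeletal muscle median from 0.028 to 0.10.

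Lists gained camera calls under some settings, and 0 of those calls stayed with an estimated correlation. The calcium handling list passed with array weights (0.24), without both arrays that stood apart (0.28) and with the covariate (0.27), with adjusted p = 0.797, 0.775 and 0.593 with an estimated correlation in camera. The smooth muscle list passed without both arrays (0.31) and with the covariate (0.34). The skeletal muscle list passed with the filter on dim genes (0.12), which left 11 of its 27 genes. Blood, endoderm and imprinted genes passed with array weights (-0.38, -0.30 and 0.12), without both arrays (-0.44, -0.43 and 0.25) and with the covariate (-0.36, -0.30 and 0.14), S phase genes without both arrays (-0.17) and with the covariate (-0.18), endothelial genes without both arrays (-0.21), epithelial genes with the filter (0.090) and fibroblast genes with the length trend removed (0.21). Without both arrays camera called 11 lists, the TGF-beta and BMP list turned to 0.086 with a call, and the ribosomal protein list turned to -0.0085 without one. The cause of these shifts was not tested. Of 665 list values under alternatives 94 had a median of changed sign, 85 of them uncalled in both settings, and of 2711 values of named genes 22 changed sign. Lists were not refitted without variance moderation or with every cluster tested.

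Whether the replicate numbers pair the arrays was not settled. Deviations of arrays with the same number correlated at 0.25, 0.00055 and -0.29 across genes. The arrays numbered 1 were each other's closest match between groups, and those numbered 2 and 3 were not. Deviations from a mean of 3 arrays are tied to each other, and 2 arrays stood apart, so this check cannot exclude pairing. With the replicate block limma gave 0 genes higher, 0 lower and 734 at an unadjusted p under 0.05, camera called 7 lists, and the median of the sarcomere list was 0.27.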

Other observations

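The refits with the gene length trend removed or without both arrays that stood apart, the tests on the share of cardiomyocytes, on 4-OHT replicate 1 alone and on the small nucleolar RNAs, the splits for single lists, and everything on the microRNAs below were chosen after the results were seen. MicroRNA genes between Dlk1 and Dio3, an imprinted region in which many microRNAs are made from maternally expressed noncoding RNAs, were higher with 4-OHT as a group. Of 43 such microRNAs on the array 39 were higher and 4 lower. Their median log2 difference was 0.43 against 0.032 for 429 other microRNAs (camera p = 6.33e-12 with the preset and 0.00135 with an estimated correlation, unadjusted). Mir376c, the member at the median, had means of 2.92 with vehicle and 3.35 with 4-OHT. Both lay below the lower quartile of every array (3.59 to 3.65), so part of this list was dim. The cluster's median exceeded that of all 10000 random lists of microRNAs of like level, of which the highest reached 0.34. Without both arrays that stood apart the cluster's median was 0.48 (camera p = 0.0158 with an estimated correlation). The set was chosen after its members' values were seen, so these p-values and this rank cannot count as a test of it. The random lists also do not keep the shared noncoding RNAs from which such microRNAs are made. Mir1197 differed by 1.07 (SE 0.23), Mir380 by 0.89 (SE 0.23) and Mir1193 by 0.79 (SE 0.20), each higher in 3 of 3 arrays, with limma adjusted p = 0.969. The noncoding RNAs Meg3 at 0.56 (SE 0.25) and Rian at 0.32 (SE 0.19), from the same region, did not pass either. Among 10 splits of the arrays the real one gave 0.43 and the highest other 0.24, and 10 splits are too few for a share under 0.05.

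Blood and heart genes varied between arrays of one group. The embryonic globin gene Hbb-y read 7.22 in vehicle replicate 2 against 10.7 and 10.8 in the other vehicle arrays, and 8.69 in 4-OHT replicate 3 against 10.8 in both other 4-OHT arrays. The heart regulators Myocd and Gata5 read 9.78 and 8.49 in vehicle replicate 2, against 7.29 and 6.46 in vehicle replicate 1 and 6.89 and 6.26 in vehicle replicate 3.

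Sarcomere genes were higher with 4-OHT by a median of 0.27, a size that 4 of the other splits of the arrays exceeded, up to 0.67. The splits at 0.67, 0.60 and 0.52 each set vehicle replicate 2, where the list lay at 0.56, beside 4-OHT arrays. They kept vehicle replicates 1 and 3 together on the other side, so these sizes rest largely on 1 array. In these arrays removing a trend with gene length did not lower the list median, so that trend did not make up the difference. The median was 0.35 (bootstrap SE 0.12) once each array's trend was removed, against a bound of 0.13 written before that refit. Leaving out single arrays moved the median, with the trend kept, from 0.033 to 0.71, far more than that SE. Whether the result would hold in other arrays is therefore undecided. A larger share of cardiomyocytes in the 4-OHT cultures may account for the higher sarcomere genes and would raise cardiac transcription factors too. The sarcomere median minus the transcription factor median was higher in all 3 arrays with 4-OHT (-0.17, 0.20 and 0.58) than with vehicle (-0.40, -0.23 and -0.30), yet the exact permutation p of 0.1 is the smallest that 3 against 3 can give, so this explanation cannot be told apart from a change within cardiomyocytes. Loss of Hdac3, a direct effect of 4-OHT and an effect of activated Cre all stay open and untested, since the design ties them together.

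G2 and M phase genes were lower with 4-OHT by a median of -0.44, a size that 1 other split of the arrays exceeded, at 0.52. In these arrays a trend with gene length did not make up the whole difference, since the median was -0.41 (bootstrap SE 0.067) with the trend removed, beyond the bound of -0.22. Leaving out single arrays moved the median, with the trend kept, from -0.72 to -0.21, far more than that SE. Whether the result would hold in other arrays is therefore undecided here too. A deviation of 4-OHT replicate 1 alone could account for about as much as remains, since without it the median was -0.21 (bootstrap SE 0.064), too close to that bound to decide. Slower division stays open and untested, and the design ties loss of Hdac3, 4-OHT itself and activated Cre together.

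Small nucleolar RNAs stood apart in vehicle replicate 2 and 4-OHT replicate 1. Loss or gain of RNA by size during extraction or labelling is a candidate explanation. Over the 6 arrays their level followed that of short against long protein-coding genes, the only relation computed. Spearman's rho was 0.943 (exact permutation p = 0.0167) and Pearson's r 0.897 (exact permutation p = 0.0375). Over the 4 arrays left without those 2, r was 0.823. The relation was computed after both measures had been seen to stand apart in the same 2 arrays. Genes of microRNAs, also short, hardly moved: the median of 478 was -0.051 in vehicle replicate 2 and 0.074 in 4-OHT replicate 1. The level of these microRNAs was not weighed, and dim genes among them could hardly fall. Rny1 and Rny3, genes of other short noncoding RNAs, did move, and were picked after their values were seen. In vehicle replicate 2 they read 7.08 and 4.14, against 12.1 to 12.5 and 9.64 to 11.3 in the other arrays. Both were highest in 4-OHT replicate 1. Level-dependent normalization is argued against, since 655 protein-coding genes of like level moved in the same direction by only a share of 0.0079 of the small nucleolar RNA deviation in vehicle replicate 2 (bootstrap SE 0.0091), and in the opposite direction in 4-OHT replicate 1 (share -0.11, bootstrap SE 0.022). Unsigned shares were tried first and left normalization undecided through 4-OHT replicate 1, and the signed form was taken after those values were seen. A biological explanation was not tested, since these arrays lie in different groups.

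Of the 10 splits of the arrays into 3 and 3, all 10 gave 0 genes past limma's adjusted threshold, like the real one, with 713 genes at an unadjusted p under 0.05 in the real split and up to 1679 in another. For gene lists 5 of the 10 splits, the real one included, gave at least the 7 lists that camera called, and the highest other split gave 16. For the sarcomere list 5 splits, the real one included, had a median as large in size (0.27 real, highest other 0.67), and 3 other splits had a smaller camera adjusted p than the real 3.09e-05, down to 6.00e-13. Median sizes, real and highest other, were 0.44 and 0.52 for G2 and M phase, 0.33 and 0.21 for p53 target, 0.24 and 0.33 for amino acid response, 0.10 and 0.17 for Hox, 0.24 and 0.29 for ribosomal protein and 0.14 and 0.19 for sterol genes. With 10 splits no share under 0.05 can be had.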
